A study of Mus musculus with 16 samples.

How the data were processed

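The libraries came from high-throughput genome-wide translocation sequencing (HTGTS), which maps the genomic ends (prey) that join to a chosen DNA break (bait). The bait was a cassette of 25 I-SceI sites in intron 1 of 1 Myc allele on chromosome 15, in splenic IgM+ B cells of 129sv mice. I-SceI came from a retrovirus. Cells were stimulated with anti-CD40 at 1 µg/mL plus IL4 at 20 ng/mL, infected after 24 h and harvested at day 4, or stimulated with an antibody to RP105 at 2 µg/mL, infected after 48 h and harvested at day 5. The ATM kinase inhibitor KU55933 was used at 10 µM.

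The deposited files list 1 junction per row with the prey position on mouse genome build mm9, the genome build per the labels. Per the file headers the files also hold an alignment score for the prey part of the read, which was not used. The older files of the deposited series hold a count of reads per junction in a column named as a PCR count, which was described only and entered no test. The authors named genes and switch regions in the files. The aligner, its version and the filters behind the lists are not given in the sources used here, and 8 junctions outside chromosome 15 repeated a prey position and strand of their library.

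Rows identical in every position column were counted once, which dropped 55 rows, and 3 rows on the mitochondrial genome and 1 fragment of a broken record were left out. This left 141168 junctions in 16 libraries, of which 33479 lay outside chromosome 15. Counts per region are numbers of junctions, whole numbers without normalization. Chromosome 15 was left out of the tests because it holds the break, whose position was taken as the median of the junctions labelled Myc, at 61819433. The rest of the genome was divided into 29 features: each chromosome without its antigen receptor loci, chromosome 12 centromeric and telomeric of Igh, the constant and switch, D-J and V parts of Igh, and the loci Igk, Igl, Tra/Trd, Trb and Trg. Locus ends came from junctions labelled with neighbouring genes, since no mm9 annotation was at hand. A second tally used 455 bins of 5 Mb with at least 20 junctions over all libraries, and another used 162 genes with at least 10 junctions, by the gene name in the files. Of the junctions outside chromosome 15, 45.0% carried no gene name.

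Counts were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, fitted to all 16 libraries with the junctions outside chromosome 15 as library size. P-values were adjusted by Benjamini-Hochberg within each comparison and tally, with a threshold of 0.05. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic. The comparisons were ATM-deficient against WT under each stimulus, KU55933 against none, ATM-deficient against KU55933, RP105 against anti-CD40/IL4 in each genotype, and the interaction, which is the genotype difference under RP105 minus that under anti-CD40/IL4. Shares of junctions per library were compared by a two-sided exact permutation test of the difference of means, adjusted over 66 tests. With 4 against 3 libraries there are 35 splits and the smallest p is 0.0286. With 3 against 3 libraries p cannot go below 0.1.

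Gene lists were fixed before the data were examined. They were 31 off-target genes of AID (the cytidine deaminase of activated B cells), 11 early replicating fragile sites, 14 long or late replicating fragile genes, 7 class switch regions and 6 markers of other cells. The loci of V(D)J recombination formed a further list and are features of the partition. Lists were tested with limma 3.58.1 camera at the preset correlation and again with an estimated correlation. The genes to be named were also fixed by rule: chromosome 12 parts, antigen receptor loci and switch regions with at least 10 junctions, up to 10 genes per direction past the threshold, up to 10 members of each of the first 3 lists with at least 10 junctions, up to 5 called bins per direction, and the 10 genes with most junctions in each group.

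The fits were tested on simulated data in which 6 of the 29 features, 91 of the 455 bins or 32 of the 162 genes changed 2-fold or 4-fold. Of those changed 4-fold, 85.0% were recovered in the partition, 44.9% among bins and 4.06% among genes for ATM-deficient against WT under anti-CD40/IL4, and 76.7%, 29.7% and 4.06% under RP105. Of those changed 2-fold, 66.7%, 2.31% and 0.625% were recovered under anti-CD40/IL4, and 75%, 0.769% and 0% under RP105, in the same order. Gene counts therefore have little power, and bin counts have little for 2-fold changes.

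Alternatives tried were TMM factors, DESeq2 1.42.0, library sizes without chromosome 12, distinct positions, leaving out only 1 Mb either side of the break site, fits to the compared groups alone, a block for the replicate number, each replicate left out in turn, other bin sizes, count minimums, denominators and windows. By default DESeq2 takes its scale only from genes with a junction in every library. In this sparse gene tally its calls and folds are therefore no independent check of those of edgeR. Added after the data were seen were fits without junctions that start in a CA repeat, which match a CA or TG repeat in at least 18 of the first 20 prey bases, without narrow clusters, with reads of a single junction, with the sequencing run as a block, and with the genotype labels of the RP105 libraries exchanged. Read names showed that the 7 anti-CD40/IL4 libraries without inhibitor were run on a 454 sequencer and the other 9 on a MiSeq. Shares and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

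Depth ranged from 4484 to 18264 junctions per library and from 586 to 5604 outside chromosome 15. Confidence intervals of a share are Wilson intervals at 95%, and a count of 0 is read as up to 3 counts. Intervals and these limits cover counting error only, since PCR products without molecular identifiers are not independent molecules. The labels do not say whether replicates are separate animals, so p-values measure only the spread between libraries.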

Results

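Junctions between I-SceI breaks in Myc and the rest of the genome were mapped in 16 libraries of stimulated mouse splenic B cells in 5 groups. The groups were WT (n = 4), ATM-deficient (n = 3) and WT with KU55933 (n = 3) under anti-CD40/IL4, and the libraries labelled WT (n = 3) and ATM-deficient (n = 3) under RP105. ATM is a kinase that signals DNA double-strand breaks, and KU55933 inhibits it. Anti-CD40/IL4 drives class switching at Igh, the heavy chain locus, to the IgG1 and IgE constant regions. RP105 is a surface protein of B cells, and antibodies to it make them proliferate. Comparisons of genotypes and of stimuli follow from the series' stated design.

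The WT anti-CD40/IL4 libraries held 6899, 5899, 8379 and 4674 junctions, of which 1307, 910, 1509 and 731 lay outside chromosome 15. The ATM-deficient anti-CD40/IL4 libraries held 7725, 8449 and 5623 junctions, with 2192, 2714 and 1912 outside chromosome 15. With KU55933 the libraries held 10528, 17035 and 18264, with 3606, 5432 and 5604 outside. The libraries labelled WT under RP105 held 7278, 4484 and 11627, with 1624, 956 and 2496 outside, and those labelled ATM-deficient held 6304, 7342 and 10658, with 586, 744 and 1156 outside. Shares below are percentages of junctions outside chromosome 15 unless another base is named, given as mean ± SD over libraries.

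In the ATM-deficient anti-CD40/IL4 libraries, junctions rose on the part of chromosome 12 centromeric of Igh and fell in Igh itself. The centromeric part, which ends where Igh begins at 114427082 on mm9, held 8.70% ± 1.38 (SD, n = 3) of junctions, against 3.17% ± 0.640 (SD, n = 4) in WT, a ratio of 2.75. The Igh locus held 6.26% ± 1.16 (SD, n = 3), against 13.1% ± 1.38 (SD, n = 4), a ratio of 0.477. Close to Igh, from 100 to 110 Mb, ATM-deficient libraries had 2.29 ± 0.492 junctions per Mb per 1000 junctions and WT had 0.449 ± 0.253, a ratio of 5.09. Chromosome 12 as a whole held 15.0% ± 0.567 and 16.4% ± 1.09, which did not separate the groups (exact permutation p = 0.143).

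Of the 29 features, edgeR called 1 higher and 1 lower: chromosome 12 centromeric of Igh with a log2 fold change of 1.48 (SE 0.14, adjusted p = 4.82e-10), and the constant and switch part of Igh (chromosome 12, 114427082 to 114664838) with -1.10 (SE 0.14, adjusted p = 1.26e-07). In the exact permutation test the centromeric share and that of Igh as a whole reached p = 0.0286, the smallest possible, with 0.118 after adjustment over 66 tests. Libraries of the groups did not overlap in either share. Within the 2 sequencing runs that held 1 library of each group, the log2 ratio of the centromeric share was 1.41 and 1.70. Of 455 bins, 2 passed the threshold, both on chromosome 12: 100 to 105 Mb with 2.10 (SE 0.48) and 105 to 110 Mb with 2.57 (SE 0.45). The first of these no longer passed without WT replicate 3 (2.09, adjusted p = 0.0523), without ATM-deficient replicate 3 (1.91, adjusted p = 0.0547) or with the run as a block (2.25, adjusted p = 0.0828). EdgeR called 4 features (2 higher, 2 lower) and 6 bins with only 1 Mb around the break left out, and the median log2 fold change of the features moved by -0.19.

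**Figure D1:**
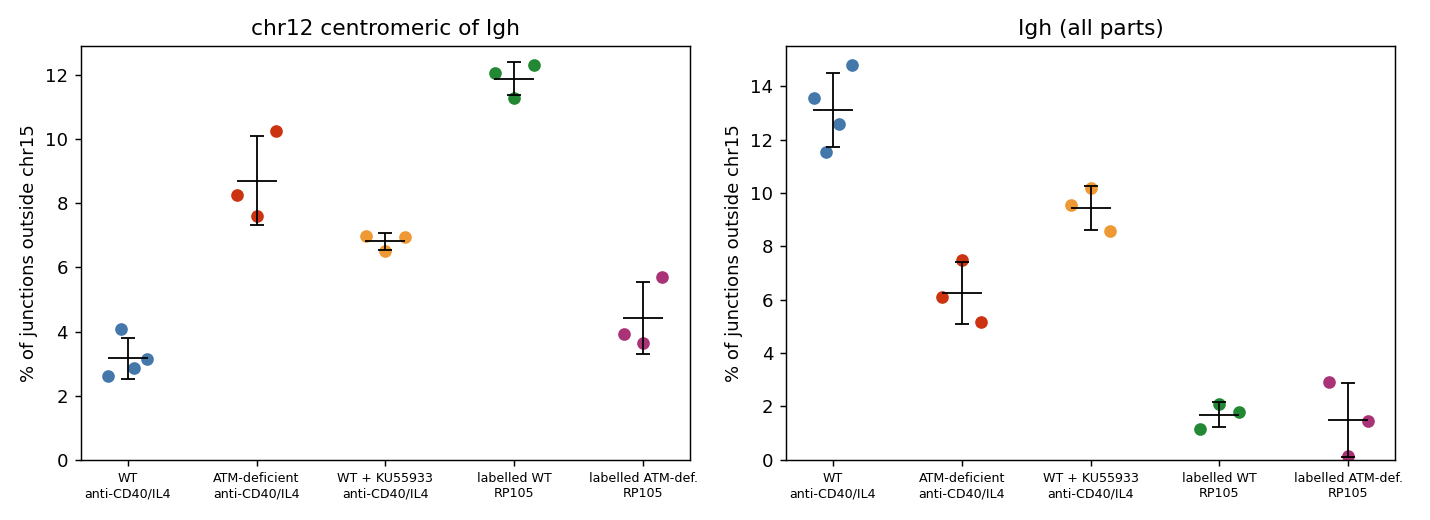
Share of junctions outside chromosome 15, in percent, on chromosome 12 centromeric of Igh (left) and in Igh (right). Each point is a library, and bars are the mean and SD; the centromeric mean was 8.70% in ATM-deficient and 3.17% in WT libraries under anti-CD40/IL4, and 4.42% and 11.9% in the libraries labelled so under RP105.

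The switch regions, the repetitive stretches where AID opens breaks during class switching, carried most Igh junctions. Smu, the donor switch region, held 1.57% ± 0.529 in ATM-deficient libraries (n = 3) and 4.81% ± 0.973 in WT (n = 4). Se, the IgE switch region, held 1.10% ± 0.263 and 4.02% ± 1.18, and Sg1, the IgG1 switch region, 1.63% ± 0.0309 and 3.05% ± 1.11. The gene tally called 0 of 162 genes by edgeR, with 8 at an unadjusted p under 0.05, 0 by DESeq2 and 0 with TMM factors. It called 2 with only the compared groups, 1 with at least 30 junctions per gene, 3 with the run as a random block and 3 with only 1 Mb around the break left out. Adjusted over the list alone, 2 of the 6 measured switch regions fell and 0 rose. Camera placed the switch regions lower than other genes (adjusted p = 0.0375), with an adjusted p = 0.213 with an estimated correlation. Of the 13 measured AID off-target genes 6 had a positive log2 fold change, with a camera adjusted p = 0.797; Il4ra, the IL4 receptor chain, had 0.22 (SE 0.58), and Pim1, a kinase, -0.09 (SE 0.61), with ranges of -0.07 to 0.52 and -1.13 to 0.37 without 1 library at a time.

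Fewer junctions stayed near the break in the ATM-deficient libraries. Of all junctions, 54.6% ± 4.24 (SD, n = 3) lay within 1 Mb of the break, against 78.7% ± 2.43 (SD, n = 4) in WT, with exact permutation p = 0.0286 and adjusted p = 0.118. Of junctions beyond 1 Mb, chromosome 15 held 30.7% ± 0.217 and 19.9% ± 1.56. Within the 2 shared sequencing runs the log2 ratio of the share within 1 Mb was -0.54 and -0.66.

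**Figure D2:**
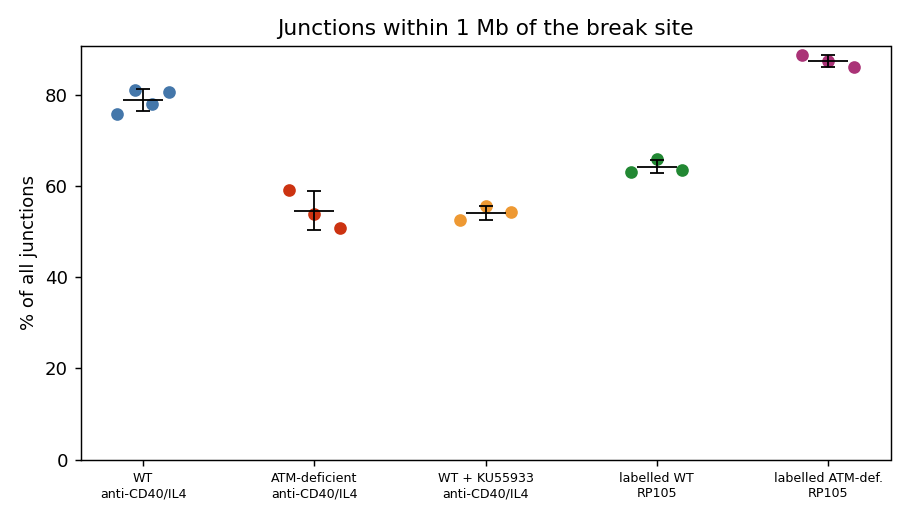
Percent of all junctions within 1 Mb of the Myc break, by group. Each point is a library with group mean and SD; the means were 78.7% in WT, 54.6% in ATM-deficient and 54.1% in inhibitor libraries under anti-CD40/IL4, and 64.2% and 87.3% in those labelled WT and ATM-deficient under RP105.

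With KU55933 in WT cells, the centromeric part of chromosome 12 again held more junctions than in untreated WT, 6.82% ± 0.260 (SD, n = 3), a ratio of 2.15. Igh held 9.43% ± 0.822 (n = 3), a ratio of 0.720, and chromosome 12 as a whole 16.4% ± 0.654. Within 1 Mb of the break lay 54.1% ± 1.53 (n = 3) of all junctions. Of the switch regions Se held 1.04% ± 0.818 (n = 3), against 4.02% ± 1.18 in WT (n = 4). Smu was also lower, with 3.07% ± 0.240 against 4.81% ± 0.973, while Sg1 held 3.44% ± 0.867 against 3.05% ± 1.11. The bin from 130 to 135 Mb of chromosome 7, which holds Il4ra and Il21r (the IL21 receptor), rose, holding 2.33% ± 0.473 of junctions in inhibitor libraries (n = 3) and 1.03% ± 0.371 in WT (n = 4).

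The edgeR fit of the 29 features called 1 higher and 2 lower: chromosome 12 centromeric of Igh with 1.14 (SE 0.14, adjusted p = 7.83e-08), the Igh constant and switch part with -0.50 (SE 0.12, adjusted p = 0.00371), and chromosome 5 with -0.36 (SE 0.11, adjusted p = 0.0251). Centromeric, Igh and 1 Mb shares each had exact permutation p = 0.0286, with 0.118 after adjustment. The bin on chromosome 7 had 1.16 (SE 0.30, adjusted p = 0.0440) and was the only one of 455 to pass. Se was the only gene past the threshold, with -1.98 (SE 0.53, adjusted p = 0.0305). DESeq2, only the compared groups and no filter called 0 genes, only 1 Mb left out called 2, at least 30 junctions 3, TMM factors 10 and the run as a random block 20. Camera placed the 13 AID off-target genes higher (adjusted p = 0.00200), with an adjusted p = 0.222 with an estimated correlation, and 0 members passed adjusted over the list alone. Among them Il4ra had 1.45 (SE 0.52), Il21r 1.59 (SE 0.63), Bcl6, a transcriptional repressor in germinal centre B cells, 1.92 (SE 0.83), and Pax5, a B cell transcription factor, 1.70 (SE 0.83), none past the threshold. Without 1 library at a time they ranged over 1.17 to 1.74, 1.34 to 1.75, 1.37 to 3.04 and 1.16 to 2.65. The 6 switch regions had a camera adjusted p = 0.765, and 1 fell adjusted over the list alone. Inhibitor libraries were run on a MiSeq and untreated ones on a 454 sequencer, so treatment and sequencer cannot be told apart. EdgeR called 8 features (2 higher, 6 lower) and 11 bins with only 1 Mb around the break left out, and the median log2 fold change of the features moved by -0.19, with -0.55 for chromosome 5. Chromosome 5 did not pass with DESeq2 (-0.35), only the compared groups (-0.36), the replicate number as a block (-0.35), CA-repeat starts removed (-0.32) or CA-repeat starts and narrow clusters removed (-0.31). The chromosome 7 bin did not pass with the replicate number as a block (1.22), single-row reads (1.12), the run as a random block (1.16) or no filter (1.16). Se did not pass with TMM factors (-1.31), DESeq2 (-1.26), only the compared groups (-1.98) or no filter (-1.98). Leaving out 1 library at a time, the threshold was no longer passed by chromosome 5 without WT replicates 1, 2 and 4 (-0.31, -0.34, -0.35) and inhibitor replicates 1 and 2 (-0.32, -0.36). The chromosome 7 bin without WT replicates 2, 3 and 4 (1.02, 1.01, 1.22) and inhibitor replicates 1 and 2 (1.04, 1.11) also no longer passed. Se without WT replicates 1 and 3 (-1.78, -1.98) and inhibitor replicates 2 and 3 (-2.03, -1.50) also no longer passed.

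Of the anti-CD40/IL4 groups, ATM-deficient and inhibitor libraries were also compared with each other. The Igh constant and switch part was lower in ATM-deficient libraries, by a log2 fold change of -0.60 (SE 0.13, adjusted p = 0.00162), as was Igk, the kappa light chain locus on chromosome 6, with -1.88 (SE 0.50, adjusted p = 0.0112). Igk held 0.165% ± 0.145 (n = 3) and 0.655% ± 0.202 (n = 3). The part of chromosome 12 centromeric of Igh was higher, with 0.34 (SE 0.10, adjusted p = 0.0193), and its bin from 105 to 110 Mb had 1.23 (SE 0.30, adjusted p = 0.0180). From 110 Mb to Igh the densities were 4.87 ± 0.669 and 5.00 ± 0.717 junctions per Mb per 1000. The share within 1 Mb of the break differed by 0.450 percentage points (exact permutation p = 0.900), ranging over -1.85 to 2.34 percentage points without 1 library at a time.

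The edgeR fits called 1 feature higher and 2 lower, 1 of 455 bins and 0 of 162 genes, with 17 genes at an unadjusted p under 0.05 and 0 by DESeq2. AID off-target genes were lower as a list (camera adjusted p = 0.0193), with an adjusted p = 0.471 with an estimated correlation; 2 fell adjusted over the list alone. Il21r had -1.85 (SE 0.60), ranging over -2.25 to -1.59 without 1 library at a time. Bcl6 had -3.01 (SE 0.87), with 2 junctions in ATM-deficient libraries, both in replicate 1, and -2.39 was its value nearest 0 without another library. Switch regions had a camera adjusted p = 0.502 and 0 members past the threshold adjusted over the list alone. Genotype, inhibitor and sequencer cannot be told apart here. EdgeR called 4 features (1 higher, 3 lower), 2 bins and 0 genes with only 1 Mb around the break left out, and the median log2 fold change of the features moved by -0.004. The centromeric part did not pass with DESeq2 (0.29). The bin at 105 Mb did not pass with TMM factors (1.15), CA-repeat starts removed (1.16) or the run as a random block (1.22). Leaving out 1 library at a time, the threshold was no longer passed by the centromeric part without ATM-deficient replicate 3 (0.22) and inhibitor replicate 2 (0.31). Igk without inhibitor replicate 2 (-1.57) also no longer passed. The bin at 105 Mb without ATM-deficient replicates 1 and 3 (1.08, 1.16) and inhibitor replicates 1 and 2 (1.20, 1.29) also no longer passed.

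Under RP105 the direction on the part of chromosome 12 centromeric of Igh was the opposite. Chromosome 12 as a whole held 6.04% ± 1.75 in the libraries labelled ATM-deficient and 13.7% ± 0.486 in those labelled WT. The libraries labelled ATM-deficient had 4.42% ± 1.13 (SD, n = 3) of junctions centromeric of Igh and those labelled WT had 11.9% ± 0.525 (SD, n = 3), a ratio of 0.372. From 100 to 110 Mb the densities were 0.598 ± 0.396 and 3.39 ± 0.440 junctions per Mb per 1000. Within 1 Mb of the break lay 87.3% ± 1.38 and 64.2% ± 1.43 of all junctions. Igh held few junctions in both groups, 1.50% ± 1.38 and 1.69% ± 0.472. Chromosomes 1 and 10 were higher and chromosome 19 lower in the libraries labelled ATM-deficient.

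In edgeR the centromeric part had a log2 fold change of -1.37 (SE 0.15, adjusted p = 1.34e-08), and the log2 ratio within the 2 runs shared by the groups was -1.58 and -1.11. The other calls were chromosome 1 with 0.66 (SE 0.11, adjusted p = 1.04e-05), chromosome 19 with -0.68 (SE 0.21, adjusted p = 0.0271) and chromosome 10 with 0.49 (SE 0.17, adjusted p = 0.0451). The Igh constant and switch part had 0.01 (SE 0.40), ranging over -0.52 to 0.48 without 1 library at a time, while the difference in Igh share ranged over -0.886 to 0.498 percentage points. The bins from 100 to 105 Mb and 105 to 110 Mb of chromosome 12 fell, with -2.17 (SE 0.53) and -2.40 (SE 0.46), and no other bin passed. The exact permutation test cannot go below p = 0.1 here, which the centromeric, whole chromosome 12, chromosome 15 and 1 Mb shares reached. The gene tally called 0 by edgeR, with 4 at an unadjusted p under 0.05, and 0 by DESeq2. AID off-target genes and switch regions each had a camera adjusted p = 0.265, with 0 members past the threshold adjusted over the list alone. With the run as a block, calls ended for chromosome 10, 0.40 (adjusted p = 0.136), chromosome 19, -0.61 (adjusted p = 0.0958), and the bin at 100 Mb, -1.91 (adjusted p = 0.0744); with a random block in limma voom they ended for chromosome 10, 0.29 (adjusted p = 0.294), and chromosome 19, -0.64 (adjusted p = 0.200). Junctions that start in a CA repeat made up 17.4% ± 2.34 in the libraries labelled ATM-deficient and 8.35% ± 1.12 in those labelled WT, and without them chromosome 10 had 0.27 (SE 0.18, adjusted p = 0.706). Without them and without narrow clusters, chromosome 1 had 0.44 (SE 0.14, adjusted p = 0.0709) and chromosome 19 had -0.57 (SE 0.21, adjusted p = 0.126). EdgeR called 13 features (11 higher, 2 lower), 11 bins and 0 genes with only 1 Mb around the break left out, and the median log2 fold change of the features moved by 0.39, with 1.06 for chromosome 1 and 0.90 for chromosome 10. Without labelled ATM-deficient RP105 replicate 3 chromosome 10 had 0.75. Chromosome 10 did not pass with TMM factors (0.49) or library sizes without chromosome 12 (0.37). Chromosome 19 did not pass with only 1 Mb around the break left out (-0.29). The bin at 100 Mb did not pass with CA-repeat starts removed (-1.98). Leaving out 1 library at a time, the threshold was no longer passed by chromosome 10 without labelled WT RP105 replicates 1, 2 and 3 (0.51, 0.50, 0.47) and labelled ATM-deficient RP105 replicates 1 and 2 (0.28, 0.48). Chromosome 19 without labelled WT RP105 replicate 1 (-0.59) and labelled ATM-deficient RP105 replicates 2 and 3 (-0.66, -0.65) also no longer passed. The bin at 100 Mb without labelled WT RP105 replicate 1 (-1.98) and labelled ATM-deficient RP105 replicates 1 and 3 (-1.78, -2.48) also no longer passed.

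**Figure D3:**
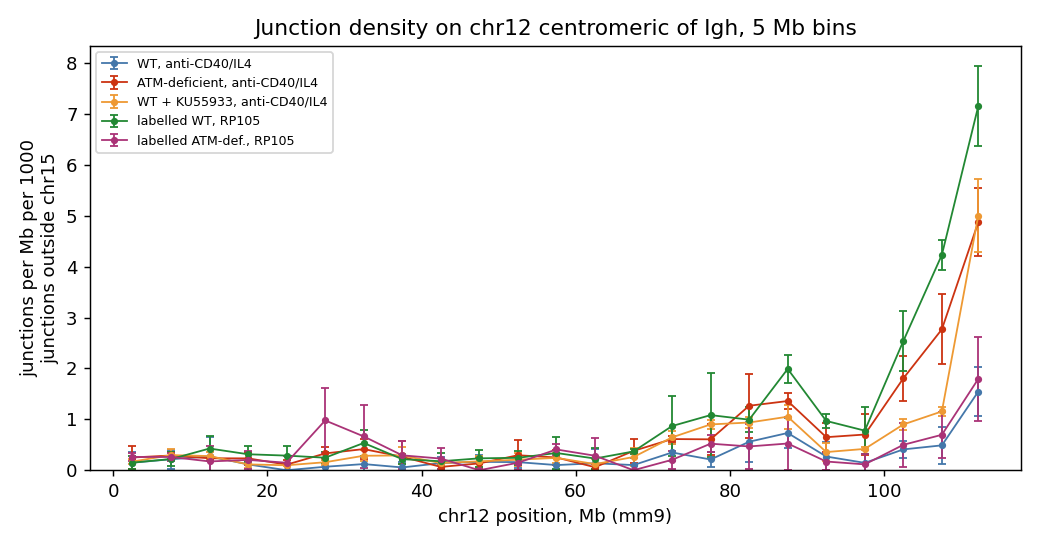
Junctions per Mb per 1000 junctions outside chromosome 15, in 5 Mb bins along chromosome 12 up to Igh (mm9). Points are group means and bars the SD over libraries; from 105 to 110 Mb the means were 0.489 in WT, 2.77 in ATM-deficient and 1.16 in inhibitor libraries under anti-CD40/IL4, and 4.23 and 0.697 in those labelled WT and ATM-deficient under RP105.

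The interaction tested whether the genotype difference was the same under both stimuli. Stimulus, infection time, harvest day and sequencer cannot be told apart in it. For chromosome 12 centromeric of Igh it was -2.85 on the log2 scale (SE 0.21, adjusted p = 5.28e-13), since the labelled genotype difference was 1.48 under anti-CD40/IL4 and -1.37 under RP105. Chromosome 1 had 0.86 (SE 0.15, adjusted p = 3.74e-05) and chromosome 19 had -0.94 (SE 0.27, adjusted p = 0.0158). Bins of chromosome 12 starting at 85, 95, 100 and 105 Mb were lower, with -2.67 (SE 0.70), -4.44 (SE 1.15), -4.27 (SE 0.71) and -4.97 (SE 0.64). The gene tally called 0 by edgeR, with 12 at an unadjusted p under 0.05, and 0 by DESeq2. No list passed, the lowest camera adjusted p being 0.839. With the genotype labels of the RP105 libraries exchanged, the interaction of the centromeric part was -0.11 (SE 0.22). EdgeR called 14 features (12 higher, 2 lower), 16 bins and 1 gene with only 1 Mb around the break left out, and the median log2 fold change of the features moved by 0.59, with 1.46 for chromosome 1. The bin at 95 Mb passed without labelled ATM-deficient RP105 replicate 3 (adjusted p = 0.00685), which held all 2.0 of that group's junctions there. Chromosome 19 did not pass with only 1 Mb around the break left out (-0.34), the run as a random block (-0.91) or CA-repeat starts and narrow clusters removed (-0.81). The bin at 85 Mb did not pass with only 1 Mb around the break left out (-2.07). The bin at 95 Mb did not pass with DESeq2 (-4.88). Leaving out 1 library at a time, the threshold was no longer passed by chromosome 19 without labelled ATM-deficient RP105 replicate 3 (-0.91). The bin at 85 Mb without WT replicate 3 (-2.40) and labelled ATM-deficient RP105 replicates 1 and 2 (-2.28, -2.58) also no longer passed. The bin at 95 Mb without WT replicate 3 (-3.89), ATM-deficient replicate 3 (-3.98), labelled WT RP105 replicate 3 (-3.93) and labelled ATM-deficient RP105 replicates 1 and 2 (-4.08, -3.96) also no longer passed.

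In WT-labelled libraries, RP105 against anti-CD40/IL4 showed fewer junctions in Igh and more centromeric of it. Igh held 1.69% ± 0.472 (SD, n = 3) under RP105 and 13.1% ± 1.38 (SD, n = 4) under anti-CD40/IL4, a ratio of 0.129. The centromeric part held 11.9% and 3.17%, a ratio of 3.76. The switch regions Smu, Sg1 and Se fell, to 0.356% ± 0.0699, 0.0873% ± 0.103 and 0.0534% ± 0.0925 (n = 3). Sg3, the IgG3 switch region, had 9 junctions under RP105 and 0 of 4457 under anti-CD40/IL4, which allows up to 0.0673%. Pooled over each group's libraries, the RP105 share was 2.63-fold that limit, or 1.74-fold without WT replicate 3 and 1.44-fold without labelled WT RP105 replicate 2. These folds leave out the counting error of the 9 junctions and are no lower bounds. EdgeR did not call Sg3 over all genes (adjusted p = 0.0814).

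The edgeR fit called 3 features higher and 1 lower. These were chromosome 12 centromeric of Igh with 1.96 (SE 0.14, adjusted p = 1.41e-13), chromosome 19 with 0.62 (SE 0.17, adjusted p = 0.0119), chromosome 11 with 0.33 (SE 0.11, adjusted p = 0.0327) and the Igh constant and switch part with -3.30 (SE 0.20, adjusted p = 6.77e-15). Of the bins 4 rose and 3 fell: chromosome 12 at 105 Mb (3.20, SE 0.43), at 100 Mb (2.63, SE 0.47) and at 85 Mb (1.57, SE 0.44), and chromosome 10 at 40 Mb (2.69, SE 0.72), against chromosome 12 at 110 Mb, which holds Igh (-1.53, SE 0.30), chromosome 10 at 100 Mb (-2.92, SE 0.85) and chromosome 8 at 95 Mb (-2.87, SE 0.73). The bin at 110 Mb of chromosome 12 also holds the end of the centromeric part. That end had 164 of its 243 junctions under RP105 and 30 of 608 under anti-CD40/IL4. In the bin at 100 Mb of chromosome 10, narrow clusters held 8 of 15 junctions under anti-CD40/IL4 and 0 of 2 under RP105. Se had -5.65 (SE 0.79, adjusted p = 1.85e-10), Sg1 -4.68 (SE 0.79, adjusted p = 2.44e-07) and Smu -3.77 (SE 0.70, adjusted p = 4.28e-06), and no gene rose. Switch regions were lower as a list (camera adjusted p = 5.47e-04), also with an estimated correlation (adjusted p = 0.0327); adjusted over the list alone, 3 fell and 1 rose. AID off-target genes were lower (camera adjusted p = 0.00119), with an adjusted p = 0.139 with an estimated correlation; 0 of the 13 had a positive fold change and 3 fell adjusted over the list alone. Il4ra had -2.56 (SE 0.81), Pim1 -2.60 (SE 0.86) and Cd83, an activation marker, -3.29 (SE 1.09). Their 4, 3 and 1 junctions under RP105 each lay in 1 library, labelled WT RP105 replicate 3, without which 0 are left; the values nearest 0 without another library were -2.04, -2.09 and -2.39. Centromeric, Igh and whole chromosome 12 shares each had exact permutation p = 0.0286, with 0.118 after adjustment. Stimulus, infection time, harvest day and sequencer cannot be told apart here, and CA-repeat starts made up 8.35% ± 1.12 and 0.568% ± 0.426. EdgeR called 14 features (2 higher, 12 lower), 17 bins and 10 genes with only 1 Mb around the break left out, and the median log2 fold change of the features moved by -0.39. Leaving out only 1 Mb around the break gave chromosome 11 -0.07 (adjusted p = 0.634) and chromosome 19 0.21 (adjusted p = 0.371), and DESeq2 ended the call of chromosome 11 (0.32, adjusted p = 0.0510). Labelled WT RP105 replicate 3 held all RP105 junctions of Se (4) and of the bin at 100 Mb of chromosome 10 (2.0), and without it both passed (adjusted p = 1.44e-08 and 0.0406). With the genotype labels of the RP105 libraries exchanged, the centromeric share would be 4.42% against 3.17%, and edgeR gave 0.59 (SE 0.20, adjusted p = 0.0298), with -3.29 (SE 0.25, adjusted p = 2.15e-12) in the Igh constant and switch part. Chromosome 19 then had -0.06 (SE 0.23, adjusted p = 0.961) and chromosome 11 0.39 (SE 0.12, adjusted p = 0.0298), and none of the bins above other than chromosome 12 at 110 Mb passed. Chromosome 11 did not pass with TMM factors (0.33), library sizes without chromosome 12 (0.29), the replicate number as a block (0.27), CA-repeat starts removed (0.27) or CA-repeat starts and narrow clusters removed (0.28). Chromosome 10 at 40 Mb did not pass with DESeq2 (2.63), only 1 Mb around the break left out (2.30) or the run as a random block (2.05). Chromosome 10 at 100 Mb did not pass with DESeq2 (-3.21), only the compared groups (-2.84), the replicate number as a block (-2.84), CA-repeat starts removed (-2.82) or single-row reads (-2.86). Chromosome 8 at 95 Mb did not pass with DESeq2 (-3.05). Chromosome 12 at 85 Mb did not pass with DESeq2 (1.50), only 1 Mb around the break left out (1.16) or the run as a random block (1.51). Leaving out 1 library at a time, the threshold was no longer passed by chromosome 11 without WT replicates 2, 3 and 4 (0.31, 0.33, 0.27) and labelled WT RP105 replicates 1, 2 and 3 (0.34, 0.31, 0.36). Chromosome 19 without WT replicate 2 (0.53) and labelled WT RP105 replicate 1 (0.53) also no longer passed. Chromosome 10 at 40 Mb without WT replicates 1 and 3 (2.22, 2.68) and labelled WT RP105 replicate 3 (1.92) also no longer passed. Chromosome 10 at 100 Mb without WT replicates 1, 2 and 4 (-2.85, -2.81, -2.87) and labelled WT RP105 replicates 1 and 2 (-2.43, -2.66) also no longer passed. Chromosome 8 at 95 Mb without WT replicate 3 (-2.67) and labelled WT RP105 replicate 3 (-2.51) also no longer passed. Chromosome 12 at 85 Mb without WT replicates 1 and 3 (1.52, 1.31) and labelled WT RP105 replicates 1 and 3 (1.51, 1.54) also no longer passed.

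**Figure D4:**
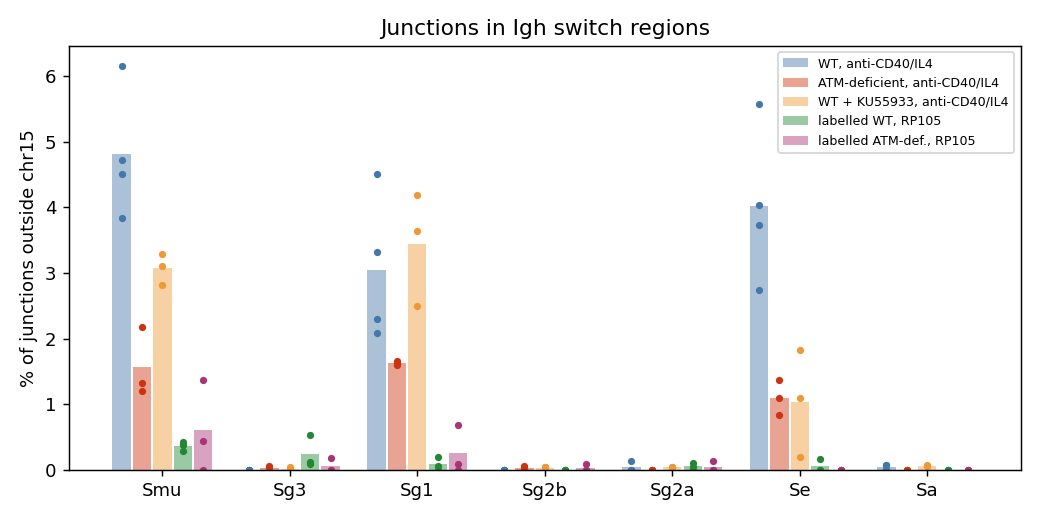
Percent of junctions outside chromosome 15 in each Igh switch region. Bars start at 0 and give group means, and points are libraries; Smu averaged 4.81%, 1.57% and 3.07% in WT, ATM-deficient and inhibitor libraries under anti-CD40/IL4 and 0.356% and 0.599% in those labelled WT and ATM-deficient under RP105.

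In the ATM-deficient label, RP105 against anti-CD40/IL4 gave fewer junctions both in Igh and centromeric of it. Igh held 1.50% ± 1.38 (SD, n = 3) and 6.26% ± 1.16 (SD, n = 3), and the centromeric part 4.42% ± 1.13 and 8.70% ± 1.38. Se had 0 of 2486 junctions under RP105, which allows up to 0.121%. Pooled over each group's libraries, that limit was 9.36-fold below the anti-CD40/IL4 share, or 5.01-fold without labelled ATM-deficient RP105 replicate 3. These folds leave out the counting error of the 77 junctions under anti-CD40/IL4. Mmp24, a metalloproteinase gene on chromosome 2, held 1.35% ± 0.169 and 0.267% ± 0.0435. Within 1 Mb of the break lay 87.3% and 54.6% of all junctions.

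By edgeR the Igh constant and switch part had -2.20 (SE 0.28, adjusted p = 1.92e-07), the centromeric part -0.89 (SE 0.15, adjusted p = 2.69e-05), chromosome 1 1.13 (SE 0.11, adjusted p = 3.16e-10) and chromosome 10 0.52 (SE 0.16, adjusted p = 0.0208). Of the bins, chromosome 12 at 110 Mb (-1.92, SE 0.37), chromosome 7 at 130 Mb (-1.88, SE 0.53) and chromosome 12 at 105 Mb (-1.76, SE 0.48) fell, and chromosome 1 at 70 Mb (2.13, SE 0.55) and at 30 Mb (1.78, SE 0.49) rose, as did the bin at 15 Mb of chromosome 1, with 6 junctions against 0. In the bin at 30 Mb, 1 narrow cluster at 31667549 to 31667696 held 16 of 23 junctions under RP105 and 8 of 18 under anti-CD40/IL4. Se (adjusted p = 6.91e-04) and Sg1 (-2.91, SE 0.86, adjusted p = 0.0361) fell and Mmp24 rose (2.31, SE 0.61, adjusted p = 0.0119). Switch regions were lower as a list (camera adjusted p = 0.00596), with an adjusted p = 0.0883 with an estimated correlation, and 2 fell adjusted over the list alone. AID off-target genes were lower (camera adjusted p = 0.00618), with an adjusted p = 0.204 with an estimated correlation and 0 past the threshold adjusted over the list alone. The exact permutation test cannot go below p = 0.1 for these shares. Stimulus, infection time, harvest day and sequencer cannot be told apart here either. EdgeR called 7 features (4 higher, 3 lower), 16 bins and 2 genes with only 1 Mb around the break left out, and the median log2 fold change of the features moved by 0.098. Sg1 had -4.43 with TMM factors, -5.28 by DESeq2 and -4.82 without labelled ATM-deficient RP105 replicate 1, and the bin at 130 Mb of chromosome 7 -3.87 without replicate 3. Without CA-repeat starts chromosome 1 had 0.45 (SE 0.13, adjusted p = 0.0130) and chromosome 10 had 0.11 (SE 0.16, adjusted p = 0.709). Without these starts and narrow clusters chromosome 1 had 0.33 (SE 0.13, adjusted p = 0.189). DESeq2 gave Mmp24 0.00, on a scale that rests on genes with a junction in every library. If Mmp24 alone set that scale, its value is 0 by construction. Other DESeq2 gene values would then carry the change of Mmp24, so they decide nothing about these genes. After the exchange of labels the direction of the centromeric part was the opposite, 11.9% against 8.70% and 0.48 (SE 0.11, adjusted p = 0.000969), while the Igh constant and switch part had -2.20 (SE 0.22, adjusted p = 2.17e-09). Chromosome 1 then had 0.47 (SE 0.10, adjusted p = 0.000753) and chromosome 10 0.03 (SE 0.14, adjusted p = 0.919), and none of the bins above passed. Chromosome 10 did not pass with library sizes without chromosome 12 (0.38), the run as a random block (0.31) or CA-repeat starts and narrow clusters removed (0.21). Mmp24 did not pass with TMM factors (0.89), the run as a random block (2.20) or no filter (2.31). Sg1 did not pass with only 1 Mb around the break left out (-2.73), the replicate number as a block (-2.95), CA-repeat starts removed (-2.65) or no filter (-2.91). Se did not pass with no filter (adjusted p = 0.135). Chromosome 12 at 105 Mb did not pass with only the compared groups (-1.75), CA-repeat starts removed (-1.79) or the run as a random block (-1.70). Chromosome 12 at 110 Mb did not pass with only the compared groups (-1.92). Chromosome 7 at 130 Mb did not pass with only the compared groups (-1.86), the replicate number as a block (-1.82) or CA-repeat starts removed (-1.62). Chromosome 1 at 15 Mb did not pass with TMM factors (adjusted p = 0.0742), DESeq2 (no adjusted p), only the compared groups (adjusted p = 0.0922) or CA-repeat starts removed (adjusted p = 0.460). Chromosome 1 at 30 Mb did not pass with TMM factors (1.33), library sizes without chromosome 12 (1.64), only the compared groups (1.78) or CA-repeat starts removed (1.77). Chromosome 1 at 70 Mb did not pass with TMM factors (1.68), DESeq2 (1.79), CA-repeat starts removed (1.40) or the run as a random block (2.08). Leaving out 1 library at a time, the threshold was no longer passed by chromosome 10 without ATM-deficient replicate 2 (0.50) and labelled ATM-deficient RP105 replicates 1 and 2 (0.31, 0.50). Mmp24 without ATM-deficient replicates 1, 2 and 3 (2.22, 2.29, 2.43) and labelled ATM-deficient RP105 replicate 3 (2.34) also no longer passed. Sg1 without ATM-deficient replicates 1, 2 and 3 (-2.92, -2.89, -2.92) and labelled ATM-deficient RP105 replicates 2 and 3 (-2.37, -2.37) also no longer passed. Se without labelled ATM-deficient RP105 replicate 3 (adjusted p = 0.0710) also no longer passed. Chromosome 12 at 105 Mb without ATM-deficient replicates 1 and 3 (-1.62, -1.69) and labelled ATM-deficient RP105 replicates 1 and 2 (-1.53, -1.58) also no longer passed. Chromosome 7 at 130 Mb without ATM-deficient replicates 1 and 2 (-1.85, -1.80) and labelled ATM-deficient RP105 replicates 1 and 2 (-1.69, -1.37) also no longer passed. Chromosome 1 at 15 Mb without ATM-deficient replicates 1, 2 and 3 (adjusted p = 0.109, adjusted p = 0.119, adjusted p = 0.0952) and labelled ATM-deficient RP105 replicates 2 and 3 (adjusted p = 0.121, adjusted p = 0.391) also no longer passed. Chromosome 1 at 30 Mb without ATM-deficient replicates 1 and 2 (1.69, 1.53) and labelled ATM-deficient RP105 replicates 1, 2 and 3 (1.64, 1.87, 1.86) also no longer passed. Chromosome 1 at 70 Mb without ATM-deficient replicates 1 and 2 (1.84, 1.82) and labelled ATM-deficient RP105 replicates 2 and 3 (1.90, 1.89) also no longer passed.

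The other antigen receptor loci held few junctions. Over all libraries Igk had 169, the D-J part of Igh 92, its V part 37, Igl 29, Tra/Trd 10, and Trb and Trg 4 each. The only one of these loci past the threshold in any comparison was Igk between ATM-deficient and inhibitor libraries. The list of early replicating fragile sites had 2 measured members, Il21r and Foxp1. Neither passed over all genes tested; adjusted over the list alone, Il21r rose with the inhibitor, and fell in ATM-deficient against inhibitor libraries and in RP105 against anti-CD40/IL4 in WT-labelled libraries. The list of long or late replicating fragile genes had 4 measured members, Fhit, Wwox, Auts2 and Park2, which held 11 or 12 junctions each; Park2 fell adjusted over the list alone, in ATM-deficient against inhibitor libraries. Camera adjusted p-values of both lists were 0.169 or more. No marker of other cells reached 10 junctions, so 0 of 6 were measured.

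Among the 10 genes with most junctions per group, Smu, Sg1, Se, Il4ra, Pim1 and Cd83 were shared by the 3 anti-CD40/IL4 groups. Under RP105, Mmp24 came first in both labelled genotypes, with 43 and 33 junctions, and Smu, Fermt2, Apbb1, Gucy2f and Plcd3 were also among the 10 of both. Smu had 17 and 13 junctions, and Sg3 with 9 was among the 10 of the label WT and Sg1 with 5 among those of the label ATM-deficient. Narrow clusters were searched for only outside Igh, so Smu could hold none. They held these numbers of the junctions of the other shared genes: Mmp24 26 of 43 and 21 of 33, Fermt2 10 of 12 and 13 of 15, Apbb1 9 of 14 and 12 of 14, Gucy2f 12 of 16 and 7 of 10, and Plcd3 10 of 10 and 9 of 9 in the libraries labelled WT and ATM-deficient. Under anti-CD40/IL4 they held 11 of 14, 15 of 18 and 16 of 24 junctions of Mmp24 and 11 of 21, 27 of 38 and 118 of 185 of Il4ra in WT, ATM-deficient and inhibitor libraries. The anti-CD40/IL4 lists also held Bcl2l1, Sh3bp5, Arid5a and Sfi1, and the RP105 lists Foxn3, Scd2, Nrxn3, Kirrel3, Crhr2 and Cdh4.

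The orientation of prey ends was compared by strand. The plus strand held 47.9% ± 6.97, 48.9% ± 3.82, 48.9% ± 2.63, 54.7% ± 1.93 and 49.5% ± 10.1 of junctions centromeric of Igh in WT, ATM-deficient and inhibitor libraries under anti-CD40/IL4 and in those labelled WT and ATM-deficient under RP105. On chromosomes other than 12 and 15 the means lay between 49.0% and 51.3%. In the Igh constant and switch part, pooled over libraries, the plus strand held 282 of 565, 196 of 406 and 663 of 1316 junctions in WT, ATM-deficient and inhibitor libraries under anti-CD40/IL4. Under RP105 it held 24 of 65 in the label WT and 7 of 32 in the label ATM-deficient. The means over these RP105 libraries were 32.8% ± 13.6 and 14.7% ± 20.0, the latter with a library of 1 junction. Their difference ranged from -29.4 to -10.7 percentage points without 1 library at a time. The smallest p that the permutations allow does not pass after adjustment, so these tests do not decide whether orientation differed.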

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

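The tests of explanations in this part, and the counts of splits, were all chosen after the results were seen.

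On the part of chromosome 12 centromeric of Igh, ATM-deficient libraries had more junctions than WT under anti-CD40/IL4, and libraries labelled ATM-deficient had fewer under RP105. Chromosome 12 as a whole did not rise in ATM-deficient libraries under anti-CD40/IL4 (15.0% against 16.4%). The genotype difference differed between stimuli for chromosome 12 centromeric of Igh (-2.85), chromosome 1 (0.86) and chromosome 19 (-0.94), and for the chromosome 12 bins from 85 Mb (-2.67), 95 Mb (-4.44), 100 Mb (-4.27) and 105 Mb (-4.97), each tested as an interaction by edgeR on the log2 scale. For the RP105 difference of the centromeric part alone, CA-repeat starts are argued against, since without them it was -1.38 (SE 0.16). So is the sequencing run, with -1.30 (SE 0.12) when blocked. Neither value covers chromosomes 1 and 19. For chromosome 1 repeat starts stay open: in RP105 libraries 36.5% of them lay there, against 6.62% of other junctions. They made up 17.4% of junctions in the label ATM-deficient and 8.35% in the label WT. Between the stimuli, sequencer, infection time and harvest day differed as well, so the interaction cannot tell these from the stimulus. An exchange of the genotype labels of the RP105 libraries stays open: turning the sign of the RP105 difference gives -0.11 (SE 0.22) with 0 of 29 features past the threshold, which restates folds already seen and is no test of the exchange. After that turn chromosome 1 (-0.46, SE 0.15, adjusted p = 0.124), the Igh constant and switch part (1.09, SE 0.41, adjusted p = 0.191) and Igk (2.30, SE 0.95, adjusted p = 0.204) lay over 2 SE from 0 without passing the threshold. Other shares also turned with the labels. Within 1 Mb of the break lay 78.7% of all junctions in WT and 54.6% in ATM-deficient libraries under anti-CD40/IL4. In the RP105 labels WT and ATM-deficient it was 64.2% and 87.3%. Of junctions beyond 1 Mb, chromosome 15 held 19.9% and 30.7%, against 39.4% and 20.1%. The Igh share fell from 13.1% to 6.26% with ATM loss but was alike in the RP105 labels, 1.69% and 1.50%. The exchange was not tested on these shares. A genotype effect that differs with the stimulus was not tested apart from that exchange and stays open.

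Chromosomes 1 and 10 held more junctions in libraries labelled ATM-deficient under RP105 than in ATM-deficient libraries under anti-CD40/IL4. Without CA-repeat starts chromosome 10 had 0.11 (SE 0.16, adjusted p = 0.709), so repeat starts may account for it. Chromosome 1 went from 1.13 (SE 0.11) to 0.45 (SE 0.13, adjusted p = 0.0130), which argues against these starts as the whole cause there but not as part of it; without narrow clusters as well it was 0.33 (SE 0.13, adjusted p = 0.189), so both together stay open. Of CA-repeat starts in RP105 libraries, 61.4% lay on chromosomes 1, 10 and 11, against 19.7% of other junctions, consistent with placement of repeats on the first chromosome names. With exchanged RP105 labels chromosome 1 had 0.47 (SE 0.10, adjusted p = 0.000753), so an exchange alone would leave an excess there. This does not count against an exchange, since the compared groups still differ in sequencer and in CA-repeat starts (8.35% against 0.429%). The 0.029 (SE 0.14) of chromosome 10 restates folds already seen. An exchange stays open for both chromosomes, as an untested biological difference between the stimuli does.

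With the inhibitor, chromosome 12 centromeric of Igh held more junctions than in WT. CA-repeat starts are argued against, with 1.14 (SE 0.14) without them. The sequencer and the inhibitor cannot be told apart, since the 1.14 compares a MiSeq with a 454 sequencer. An effect of ATM inhibition stays open.

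A library lay far from the others of its group in 2 of 31 quantities examined in WT anti-CD40/IL4 libraries, and chance gives about 1 in 20 groups. Replicate 2 had 46.6% of Igh constant and switch junctions on the plus strand, and replicate 4 had 14.4% of junctions beyond 1 Mb on chromosome 12.

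Splits of the compared libraries were fitted to those libraries alone, and the count of the real split is given against the highest of the others. Only the real split gave as many calls for ATM loss in bins 3 against 2 (1 of 35 splits as large). So it did for the stimulus in WT-labelled libraries in features 4 against 1 (1 of 35 splits as large), bins 6 against 2 (1 of 35 splits as large) and genes 3 against 0 (1 of 35 splits as large). These shares argue against chance, unadjusted for the number of counts examined. The splits ignore the sequencing run, and fewer ATM-loss bins passed with it as a block. The interaction had features 4 against 3 (1 of 100 splits as large) and bins 4 against 3 (1 of 100 splits as large). Its splits regroup genotype within each stimulus, so they cannot tell an interaction from a genotype effect. The fit to all 16 libraries called 3 interaction features, no more than the highest other split. For genes with ATM loss, 2 against 1 (1 of 35 splits as large) speaks against chance only in this fit, where Se (-1.87, adjusted p = 1.36e-05) and Smu (-1.57, adjusted p = 0.000252) passed, since the fit to all 16 libraries called 0 genes; it called 2 of the 3 bins. Chance cannot be excluded for the number called with ATM loss in features 2 against 2 (2 of 35 splits as large) or with the inhibitor in features 2 against 2 (3 of 35 splits as large), bins 1 against 1 (5 of 35 splits as large). These counts do not test the centromeric share itself, for which no other of the 35 splits gave as large a difference with ATM loss or with the inhibitor (exact permutation p = 0.0286 in both, 0.118 after adjustment). A real count of 0 makes every split as large by construction and decides nothing, as for genes with the inhibitor (35 of 35 splits, highest other 1), in the interaction (100 of 100), with ATM loss against the inhibitor (10 of 10) and with the genotype under RP105 (10 of 10). Splits were too few for a share under 0.05 for ATM loss against the inhibitor (features 3 against 0 (1 of 10 splits as large), bins 1 against 0 (1 of 10 splits as large)), for the genotype under RP105 (features 4 against 0 (1 of 10 splits as large), bins 2 against 1 (1 of 10 splits as large)) and for the stimulus in ATM-deficient libraries (features 4 against 0 (1 of 10 splits as large), bins 1 against 0 (1 of 10 splits as large), genes 5 against 0 (1 of 10 splits as large)).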

How the results depend on the processing

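The run blocks, the removal of CA-repeat starts and of narrow clusters, single-row reads and the exchange of labels were chosen after the data were seen. Counts below are those past the threshold, and names are short: ATM loss and inhibitor are against WT under anti-CD40/IL4, RP105 genotype compares the labelled genotypes, and each stimulus comparison is RP105 against anti-CD40/IL4. Chromosome 12 centromeric of Igh, by log2 fold change, stayed past the threshold without any 1 library for ATM loss (1.36 to 1.61), inhibitor (1.05 to 1.27), RP105 genotype (-1.67 to -1.24), stimulus in WT (1.87 to 2.08), stimulus in ATM-deficient (-1.19 to -0.76) and interaction (-3.15 to -2.72).

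With TMM factors, bins numbered ATM loss against inhibitor 0 and RP105 genotype 4. Genes numbered inhibitor 10 and stimulus in ATM-deficient 9. With DESeq2, bins numbered stimulus in WT 3. Genes numbered inhibitor 0, stimulus in WT 9 and stimulus in ATM-deficient 14, on a scale set only by genes with a junction in every library. These gene counts therefore do not check those of edgeR. Chromosome 12 centromeric of Igh gave ATM loss against inhibitor 0.29. Igh constant and switch part gave interaction 1.14. With only the compared groups in the fit, bins numbered stimulus in ATM-deficient 1. Genes numbered ATM loss 2, inhibitor 0 and stimulus in ATM-deficient 5. With only 1 Mb around the break left out, features numbered ATM loss 4, inhibitor 8, RP105 genotype 13, stimulus in WT 14, stimulus in ATM-deficient 7 and interaction 14. Bins numbered ATM loss 6, inhibitor 11, ATM loss against inhibitor 2, RP105 genotype 11, stimulus in WT 17, stimulus in ATM-deficient 16 and interaction 16. Genes numbered ATM loss 3, inhibitor 2, stimulus in WT 10 and interaction 1. Igh constant and switch part gave interaction 1.72. Chromosome 11 gave stimulus in WT -0.073. With no filter, bins numbered inhibitor 0. Genes numbered inhibitor 0 and stimulus in ATM-deficient 0. With at least 30 junctions per gene, genes numbered ATM loss 1, inhibitor 3, ATM loss against inhibitor 2, stimulus in WT 11 and stimulus in ATM-deficient 6. In 1 Mb bins, bins numbered inhibitor 5, RP105 genotype 1, stimulus in WT 15, stimulus in ATM-deficient 2 and interaction 8. In 10 Mb bins, bins numbered ATM loss 1 and stimulus in ATM-deficient 11. With the replicate number as a block, features numbered interaction 5. Bins numbered inhibitor 0. Genes numbered ATM loss against inhibitor 2. Igh constant and switch part gave interaction 1.08. The whole chromosome 12 share gave stimulus in WT -2.17. The centromeric share gave ATM loss 5.53, inhibitor 3.64 and stimulus in WT 8.72. The Igh share gave ATM loss -6.30, inhibitor -3.12 and stimulus in WT -10.9. Over junctions beyond 1 Mb, the whole chromosome 12 share gave ATM loss -2.68 and inhibitor -1.52. With Igh left out, the whole chromosome 12 share gave ATM loss 5.62, inhibitor 4.01 and stimulus in WT 8.46. With an estimated correlation, the camera p of AID off-target genes gave inhibitor 0.0555, ATM loss against inhibitor 0.118, stimulus in WT 0.0693 and stimulus in ATM-deficient 0.102. The camera p of class switch regions gave ATM loss 0.0532 and stimulus in ATM-deficient 0.0221. Without CA-repeat starts, the whole chromosome 12 share gave stimulus in WT -2.17. The centromeric share gave stimulus in WT 9.17. The chromosome 15 share gave stimulus in WT -3.36. The share within 1 Mb of the break site gave stimulus in WT -13.4. Without CA-repeat starts and narrow clusters, features numbered RP105 genotype 1 and stimulus in ATM-deficient 2. With the run as a block, features numbered RP105 genotype 2. Bins numbered ATM loss 1 and RP105 genotype 1. With the run as a random block in limma voom, features numbered RP105 genotype 2. Bins numbered inhibitor 0 and ATM loss against inhibitor 0. Genes numbered ATM loss 3, inhibitor 20, stimulus in WT 11, stimulus in ATM-deficient 5 and interaction 1. With single-row reads, bins numbered inhibitor 0. With the RP105 genotype labels exchanged, bins numbered stimulus in ATM-deficient 1. Chromosome 12 centromeric of Igh gave stimulus in ATM-deficient 0.48. Chromosome 19 gave stimulus in WT -0.061. The bin at 85 Mb of chromosome 12 gave stimulus in WT -0.089. The bin at 105 Mb of chromosome 12 gave stimulus in ATM-deficient 0.64. Reversed, among values past the threshold in the report or in the alternative, were the whole chromosome 12 share of the inhibitor over junctions beyond 1 Mb, that of ATM loss and of the stimulus in WT with Igh left out, chromosome 11 with only 1 Mb left out, and 4 stimulus values with exchanged labels: the centromeric part and the bin at 105 Mb in ATM-deficient, and chromosome 19 and the bin at 85 Mb in WT. Of the chromosome 12, Igh, break site and strand values that passed in neither, these turned sign. The Igh constant and switch part of the RP105 genotype, 0.009 in the report, was -0.019 with DESeq2, -0.11 with library sizes without chromosome 12, -0.15 with the run as a block and -0.50 as a random block. The whole chromosome 12 share of ATM loss against inhibitor went from -1.41 to 1.61 percentage points with Igh left out, and the Igh share of the RP105 genotype from -0.186 to 0.186 over junctions beyond 1 Mb. The share telomeric of Igh of the stimulus in WT went from 0.0132 to -0.0143 with the replicate number as a block and -0.00771 beyond 1 Mb. Without CA-repeat starts the plus-strand share of the centromeric part went from -0.0209 to 0.0402 for ATM loss against inhibitor and from 0.568 to -0.0487 for the stimulus in ATM-deficient. The centromeric share kept its direction over junctions beyond 1 Mb but was smaller: ATM loss 3.49 instead of 5.53, inhibitor 2.25 instead of 3.65, ATM loss against inhibitor 1.24 instead of 1.88, RP105 genotype -3.68 instead of -7.47, stimulus in WT 4.66 instead of 8.72 and stimulus in ATM-deficient -2.51 instead of -4.28 percentage points. Leaving out only 1 Mb moved the median log2 fold change of all features by -0.19 for ATM loss, -0.19 for the inhibitor, 0.39 for the RP105 genotype, -0.39 for the stimulus in WT and 0.59 for the interaction. Other causes were not tested.

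Without 1 library at a time, values had these ranges. Features ranged over ATM loss against inhibitor 1 to 5, RP105 genotype 2 to 3 and stimulus in WT 2 to 4. Bins ranged over ATM loss 1 to 2, inhibitor 0 to 2, ATM loss against inhibitor 0 to 4, RP105 genotype 1 to 2, stimulus in ATM-deficient 1 to 4 and interaction 2 to 6. Genes ranged over inhibitor 0 to 4, ATM loss against inhibitor 0 to 1, stimulus in WT 3 to 6 and stimulus in ATM-deficient 0 to 5. Chromosome 12 centromeric of Igh ranged over ATM loss against inhibitor 0.22 to 0.44. Igh constant and switch part ranged over interaction 0.58 to 1.58. The whole chromosome 12 share ranged over stimulus in WT -2.97 to -2.17. The centromeric share ranged over ATM loss 4.76 to 6.09, inhibitor 3.46 to 3.95 and stimulus in WT 8.52 to 9.02. The Igh share ranged over ATM loss -7.47 to -6.30, inhibitor -4.20 to -3.12 and stimulus in WT -11.9 to -10.9. The chromosome 15 share ranged over ATM loss -16.1 to -13.2, inhibitor -16.1 to -14.3 and stimulus in WT -5.34 to -4.17. The share within 1 Mb of the break site ranged over ATM loss -26.5 to -22.3, inhibitor -25.7 to -23.9 and stimulus in WT -15.6 to -13.9. These ranges crossed 0: Igh constant and switch part for RP105 genotype -0.52 to 0.48; the whole chromosome 12 share for inhibitor -0.199 to 0.605; the Igh share for RP105 genotype -0.886 to 0.498; the share of chromosome 12 telomeric of Igh for ATM loss -0.0351 to 0.0159, RP105 genotype -0.0522 to 0.0822, stimulus in WT -0.0143 to 0.0367 and stimulus in ATM-deficient -0.0314 to 0.103; the chromosome 15 share for ATM loss against inhibitor -0.789 to 2.03; the share within 1 Mb of the break site for ATM loss against inhibitor -1.85 to 2.34; the plus-strand share of chromosome 12 centromeric of Igh for ATM loss -2.42 to 2.74, inhibitor -2.40 to 2.63, ATM loss against inhibitor -2.03 to 1.77 and stimulus in ATM-deficient -4.33 to 5.73; the plus-strand share of the Igh constant and switch part for inhibitor -1.30 to 2.72; the plus-strand share of chromosomes other than 12 and 15 for ATM loss -1.38 to 0.000847. Share tests without a library, or within replicate blocks, cannot reach 0.05 by construction. Of the replicate numbers, no contrast had correlations above 0.1 in all 3 replicates, so they give no pairing. Assigning genes by body and 2 kb upstream was not run, since genes are those named in the junction lists. Depth limits small loci: the 2486 junctions of the libraries labelled ATM-deficient under RP105 leave a locus at 0 with up to 0.121%.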

Other observations

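The comparison of narrow clusters with the I-SceI site was chosen after the clusters were seen.

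Outside chromosome 15 and Igh, and without CA-repeat starts, junctions formed 51 clusters of at least 10 within 200 bp. Of these, 10 (19.6%) held a stretch matching at least 12 of the 18 bases of the I-SceI site, against 135 of 2000 random stretches (6.75%; Fisher exact p = 0.00235). Cutting by I-SceI at sites like its own is a candidate explanation for some of them, and 3 matched more bases than any random stretch (maximum 14). Clusters in Mmp24, Fermt2, Apbb1 and Gucy2f matched 13, 13, 14 and 14 bases, and the cluster in Plcd3 matched 8. Cluster sequence was rebuilt from reads, and bases without a read could not match. Plcd3 had 93 bases covered, against 150 in every random stretch, so its low match decides nothing. Some clusters lie side by side in 1 gene, as in Il4ra and Pim1. The Fisher test counts them as separate and compares unlike coverage, so its p-value is only a rough guide.

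Junctions starting in a CA repeat made up 0.568%, 0.429%, 2.80%, 8.35% and 17.4% of those outside chromosome 15 in WT, ATM-deficient and inhibitor libraries under anti-CD40/IL4 and in those labelled WT and ATM-deficient under RP105. In MiSeq libraries 62.1% of these starts lay on chromosomes 1, 10 and 11, and in 454 libraries 21.2% of 52. Of junctions beyond 1 Mb, chromosome 15 held 19.9%, 30.7%, 29.7%, 39.4% and 20.1% in the same order of groups.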
